A study of Mus musculus with 12 samples.

How the data were processed

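Gene expression was measured in striatal tissue of mouse embryos at embryonic day 18.5, with 1 array for each of 12 embryos. Per the labels' protocols, the striata of both hemispheres were dissected in ice-cold saline, total RNA was extracted with Trizol and labelled with biotin, so each array held 1 colour. The 6 wild-type (WT) and 6 knockout animals were on the C57BL/6J background. The knockout group carried Nestin-Cre and lacked Foxp1 according to the sample titles, and is called cKO here. The titles describe the 6 samples of each group as biological replicates.

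The deposited values were RMA expression values on the log2 scale, per the submitters' processing notes, which name RMA without a version. RMA corrects the background, puts the arrays on a common distribution and summarises the probes of each probe set. Array model, scanner, probe-to-gene definition and software were not given in the sources used here. The single deposited table held 25428 probe sets, each named by a gene identifier and present once per gene. The sorted values of the 11 arrays other than cKO replicate 1 agreed to within 0.000977 log2 units. Those of cKO replicate 1 differed from those of cKO replicate 2 by at most 0.00187. The columns had thus been given a shared distribution before deposit. A change common to all genes would therefore not be visible. All arrays had a median of 5.71, and values ran from 5.21 to 13.99. RMA also compresses differences near the lower end, so fold sizes of dim genes are likely to be understated. Detection p values and scan dates were not used here, and the number of arrays limits the precision.

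A symbol was given to 24674 probe sets from the platform annotation, updated through gene identifiers in a RefSeq gene table of the GRCm38.p6 assembly. No probe set carried several symbols, and 754 stayed unnamed. No coordinates are given, because no genome build was named for the array.

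Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the values as deposited, over all probe sets and all 12 arrays, without covariates. Adjusted p values are Benjamini-Hochberg values over all 25428 probe sets, with a threshold of 0.05 and no fold minimum. Changes are cKO minus WT in log2 units, with limma's standard error (SE) and 95% intervals. The median residual SD was 0.0469 log2 units.

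Before the data were examined, 40 gene lists with 633 genes were fixed, covering striatal neuron classes, other cell types of the region, signalling pathways and functional families. Of these genes 589 were measured, 3 of the list symbols being older names that were updated. The 37 lists with at least 5 measured genes were tested with camera at the preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 37. Camera with a correlation estimated for each list and fry were run beside it. A list's mean level per array was also compared between groups by a two-sided exact permutation test over all 924 assignments of the arrays, which was added after the data were seen. Its smallest possible p is 0.00216. For members of a list, calls adjusted over the list alone are given beside those over all genes.

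The genes named in the text follow a rule fixed beforehand. It takes the Foxp genes, then the 12 largest rises and 12 largest falls among genes past the threshold. Predicted genes, olfactory and vomeronasal receptors and small RNAs were left out of these. From each list it takes up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passed. Genes named outside the rule are identified as such.

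The test was tried on simulated data with the group sizes and spreads of these arrays, in 10 simulations with 200 changed probe sets among 25428. It recovered 80.3% of changes of 0.25 log2 units, 97.5% of 0.5 and 100% of 1, with 5.3% false calls. The changed probe sets were drawn from all levels, dim ones included, each with its own spread. These shares are averages and do not hold for genes with a wide spread. The compression of changes near the floor was not simulated. In the real data 170 of the 185 called probe sets lay above the median level. In the real data Gabra2, at 0.54 ± 0.14 (SE), did not pass (limma adjusted p = 0.116). A list shifted by -0.2 was found in 10 of 10 simulations, and 0.690% of unshifted lists were called. Genes were simulated as independent, so these list figures do not cover correlated genes.

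The alternatives fixed beforehand were quantile normalization again, median centring, leaving out dim probe sets, a trended robust prior, array weights, the replicate number as a block, the level of Y-linked genes as a covariate, leaving out each array, testing named genes only, a 1.5-fold minimum, an adjusted p below 0.01, estimated correlations, fry and camera on ranks. The Y-linked covariate used 3 genes and not the 4 planned. After the data were seen, cyclic loess, leaving out the 2 arrays least correlated with their group, a cortical neuron covariate and the exact permutation of list means were added.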

Results

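The data set holds the striatal transcriptomes of 12 mouse embryos at embryonic day 18.5, 6 WT and 6 cKO, measured on 1 array each. In the cKO group, Cre recombinase under control of Nestin, which is active in neural progenitors, was combined with loss of Foxp1, a forkhead transcription factor abundant in striatal projection neurons. The comparison asks which striatal transcripts differ in level between the genotypes shortly before birth. All values are RMA log2 expression, and 25428 probe sets were compared. Correlations between arrays ran from 0.992 to 0.998, and no pair of columns was identical.

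Foxp1 itself fell in the cKO striatum. Its log2 expression was 11.14 ± 0.17 (SD, n = 6) in WT and 10.23 ± 0.08 (SD, n = 6) in cKO, a change of -0.91 ± 0.07 (SE), or 1.88-fold lower (limma adjusted p = 0.000170). WT replicates 1 to 6 read 11.01, 11.17, 11.13, 11.23, 10.89 and 11.39. The cKO replicates 1 to 6 read 10.24, 10.14, 10.21, 10.36, 10.25 and 10.18, so all 6 lay below the lowest WT array. The labels do not give the deleted exons or the positions of the probes, so the size of the fall does not measure how much functional transcript was left. Among the other Foxp genes, the log2 change was 0.11 ± 0.04 for Foxp2 (adjusted p = 0.372), -0.31 ± 0.09 for Foxp4 (adjusted p = 0.181) and -0.02 ± 0.02 for Foxp3 (adjusted p = 0.741). Adjusted over the list alone, 2 of the 4 Foxp genes were lower, Foxp1 and Foxp4 (adjusted p = 0.00925 for Foxp4), and 1 was higher, Foxp2 (adjusted p = 0.0366). The WT and cKO arrays did not overlap for Foxp4.

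Beyond Foxp1, Pde7b, a cAMP phosphodiesterase, fell by 1.11 ± 0.13 (SE) on the log2 scale, from 10.26 ± 0.33 (SD, n = 6) to 9.15 ± 0.09 (SD, n = 6), or 2.16-fold. Foxo1, a forkhead factor, fell by 1.08 ± 0.17 and Nexn, an actin-binding protein, by 1.06 ± 0.17. Tenm2, a teneurin of the synaptic surface, fell by 1.05 ± 0.06 and had the smallest adjusted p of all probe sets (4.46e-05). The most increased transcripts were Plekhh2, which rose by 0.93 ± 0.09 or 1.91-fold, Npy1r, a neuropeptide Y receptor (0.76 ± 0.09), and Dlk1, a non-canonical Notch ligand (0.68 ± 0.06).

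In total 185 probe sets passed an adjusted p of 0.05, 76 higher and 109 lower in cKO, and 176 of them carried a symbol. At an unadjusted p under 0.05 there were 2729. Most changes were small: the median change was -0.32 among the lower and 0.26 among the higher probe sets. At least 1.5-fold changes were found in 30 probe sets, 24 lower and 6 higher. A change of at least 2-fold was found in 5, all of them lower. The largest fall of all was in a probe set without a symbol, which is left unnamed and out of the ranking of named genes. The other falls among the 12 largest with a name were in the cadherin Cdh8 (-0.96), the plexin Plxnd1 (-0.95), Neto1, an auxiliary subunit of kainate receptors (-0.91), the transcription factor Sox8 (-0.89), the contactin Cntn5 (-0.88), the neurofilament light chain gene Nefl (-0.76) and the glypican Gpc6 (-0.75). The other 9 of the 12 largest rises were in Cntn3 (0.67), the extracellular matrix gene Tnr (0.62), Peg10 (0.59), the zinc finger gene Zfp521 (0.58), the transcription factor Maf (0.57), the atypical cadherin Fat4 (0.57), Crim1 (0.50), the potassium channel gene Kcnh1 (0.50) and Sez6 (0.45). The total was 106, 109 and 117 without cKO replicate 2, 5 or 3, and the higher probe sets numbered 40, 40, 39, 49 and 50 without cKO replicate 2, 5, 3 or 6 or WT replicate 4. It was 278 when dim probe sets were left out, and 124, with 45 higher, without WT replicates 3 and 6, the arrays least correlated with their group and left out after the data were seen. Calls near the threshold were those of Nefl and Crim1, each passing in 9 of 19 alternatives, Fat4 (11 of 19) and Kcnh1 (4 of 19). Nexn had an adjusted p of 0.0535 without cKO replicate 2, and Zfp521 one of 0.0904 without WT replicates 3 and 6. With the replicate number as a block, the rises of Npy1r, Cntn3, Tnr, Peg10, Zfp521, Maf, Fat4, Crim1 and Kcnh1 missed the threshold. Their limma adjusted p then ran from 0.0535 (Peg10) to 0.1665 (Kcnh1). The rises of Plekhh2, Dlk1 and Sez6 passed. Among the 12 largest falls, Foxo1 (0.0900), Nexn (0.119) and Nefl (0.159) missed it, and the others passed.

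**Figure D1:**
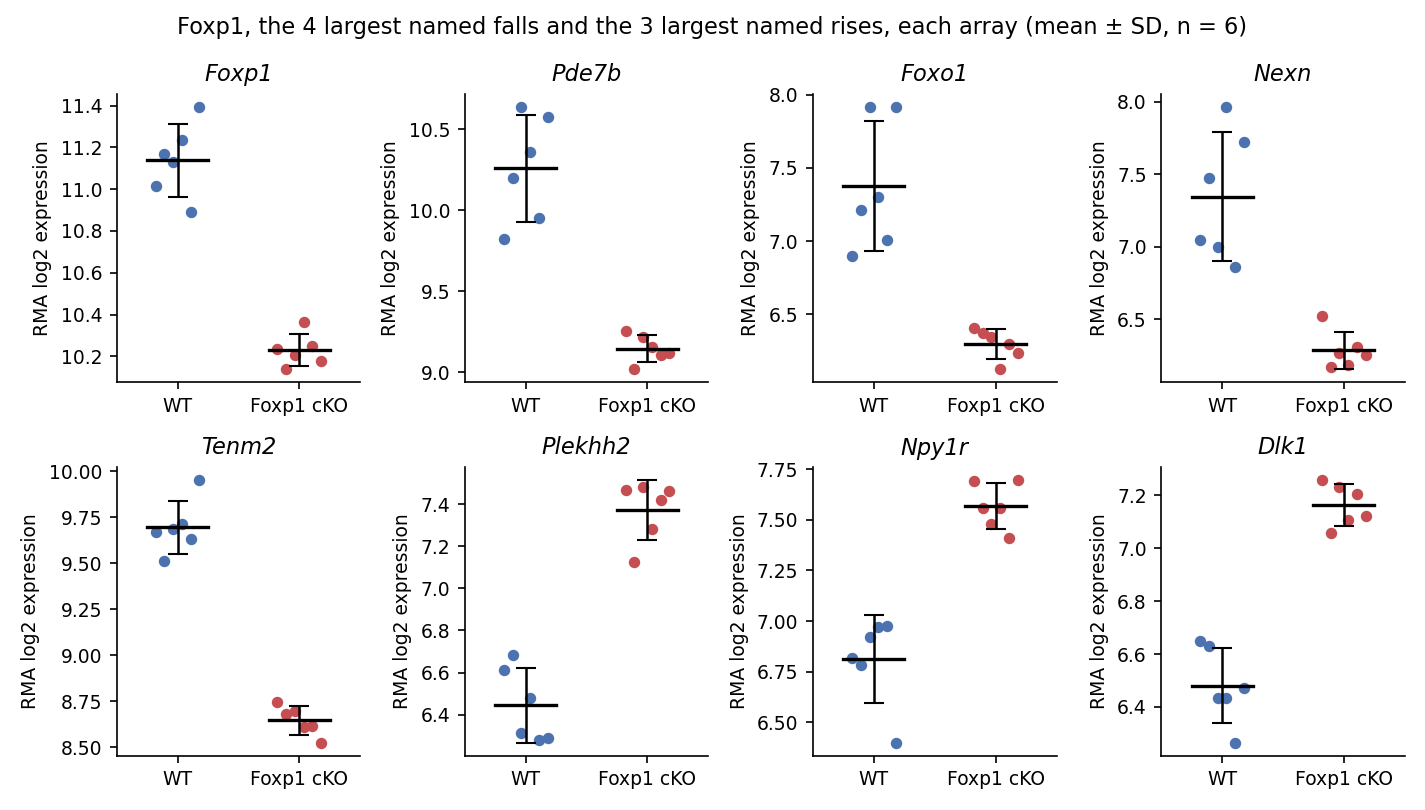
RMA log2 expression of Foxp1, the 4 other named genes with the largest falls and the 3 with the largest rises, on each of the 6 WT and 6 cKO arrays. Points are arrays, the wide bar is the group mean and the error bar its SD; axes do not start at 0. For each gene the WT and cKO arrays did not overlap, as for 169 of all 185 probe sets past the threshold.

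**Figure D2:**
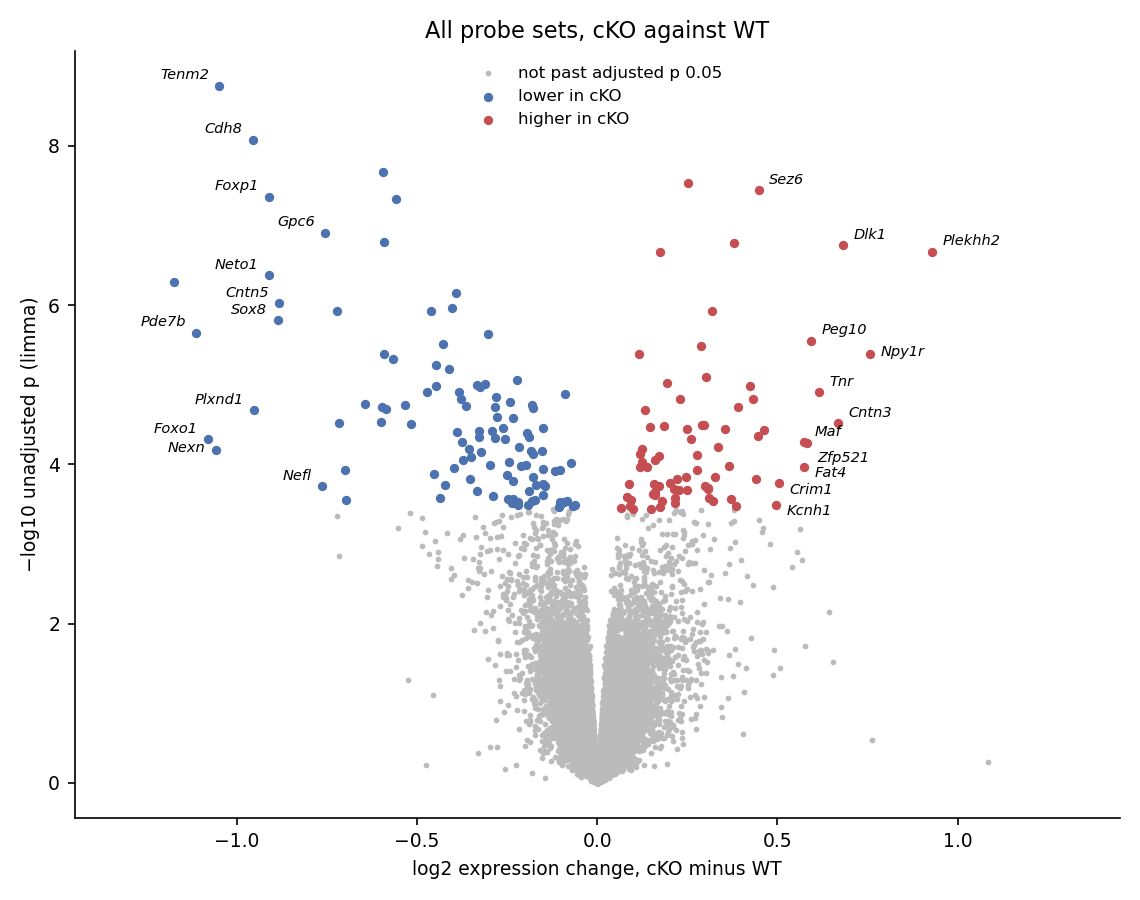
Change of each of the 25428 probe sets (x axis, log2 units, cKO minus WT) against -log10 of the unadjusted limma p (y axis). The 76 higher and 109 lower probe sets past an adjusted p of 0.05 are coloured, and Foxp1 and the 12 largest named rises and falls are labelled.

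Genes that mark striatal projection neurons were lower in cKO as a group by camera with the preset correlation. Of 24 measured genes of this list, 3 fell and 0 rose: Foxo1, the Ikaros factor Ikzf1 (-0.59 ± 0.07) and the phosphodiesterase Pde10a (-0.59 ± 0.09), which is highly enriched in these neurons. Adjusted over the list alone, 13 were lower and 3 higher. The median change was -0.20 and camera gave an adjusted p of 4.89e-07 with the preset correlation, against an adjusted p of 0.347 with an estimated correlation. The list mean was 8.55 ± 0.13 (SD, n = 6) in WT and 8.33 ± 0.05 (SD, n = 6) in cKO (exact permutation adjusted p = 0.0320), while by fry the list missed the threshold (adjusted p = 0.0863). On the same arrays the cortical neuron list described below averaged 6.75 ± 0.11 (SD, n = 6) in WT and 6.87 ± 0.17 (SD, n = 6) in cKO. Among genes singled out after their values were seen, the value was -0.55 for the tachykinin gene Tac1 (adjusted p = 0.0653), 0.04 for the dopamine receptor gene Drd1 (adjusted p = 0.956) and 0.04 for Drd2 (adjusted p = 0.896).

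The list of dopamine and cAMP signalling was also lower. Of 22 measured genes, 2 fell, Pde7b and Pde10a, and 0 rose, with 9 lower and 0 higher when adjusted over the list alone. The median change was -0.17, with an adjusted p of 1.39e-08 by camera and an adjusted p of 0.347 with an estimated correlation. It shares Drd1, Drd2, Adcy5, Gnal, Gng7, Pde10a, Pde1b, Ppp1r1b and Rgs9 with the projection neuron list, and is not independent of it. Its mean was 8.30 ± 0.10 (SD, n = 6) in WT and 8.08 ± 0.05 (SD, n = 6) in cKO (exact permutation adjusted p = 0.0320), and all 6 cKO arrays lay below every WT array. The retinoic acid list was lower in the same test (median -0.032, adjusted p = 0.0211, and adjusted p = 0.347 with an estimated correlation). Of its 17 measured genes, Rarb and Meis2 are also on the projection neuron list. The retinoid receptor gene Rxrg fell by 0.70 ± 0.14, 0 rose, and 4 were lower when adjusted over the list alone. The list's adjusted p was 0.0524 and 0.101 without WT replicate 2 or 6, 0.0618 and 0.0568 without cKO replicate 4 or 6, and 0.119 without WT replicates 3 and 6. It was 0.178 by camera on ranks, 0.106 by fry and 0.125 with the cortical covariate described below, and the call held in 14 of 23 alternatives. Rxrg passed in 6 of 19 alternatives.

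Markers of the direct and indirect pathways, the output routes of the striatum, gave no list call. The direct-pathway (D1) list had a median of -0.056 (adjusted p = 0.0526) and 1 of 10 measured genes rose, Zfp521, which is also on the matrix list and had an adjusted p of 0.0904 without WT replicates 3 and 6. With p values adjusted over the list alone, 4 were lower and 1 higher. The list passed without WT replicate 1, 5 or 6 (adjusted p = 0.0272, 0.0341 and 0.0375) or cKO replicate 3 (adjusted p = 0.0114). It also passed with array weights (adjusted p = 0.0464), with the Y-linked level as a covariate (adjusted p = 0.0231) and with cyclic loess, added after the data were seen (adjusted p = 0.0478). The indirect-pathway (D2) list had a median of 0.061 (adjusted p = 0.394), and 0 of 8 measured genes passed over all genes in limma. At an unadjusted p under 0.05, and also adjusted over the list alone, 3 were higher and 2 lower. Its members with the smallest p were the enkephalin gene Penk, at 0.38 ± 0.08 (adjusted p = 0.0501), and the transcription factor gene Six3, at 0.37 ± 0.08 (adjusted p = 0.0601). Both passed without WT replicate 3 (adjusted p = 0.00986 and 0.0407), with dim probe sets left out (0.0142 and 0.0192) and with a trended, robust prior (0.0105 and 0.0173). Penk also passed with array weights (adjusted p = 0.0261) and without WT replicates 3 and 6 (adjusted p = 0.0223). The striosome list had a median of -0.053 (adjusted p = 0.380) and the matrix list 0.089 (adjusted p = 0.140). In limma 0 of 8 striosome genes passed over all genes, with 2 higher and 2 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. Nr4a1, on that list, had a value of -0.22 (adjusted p = 0.145). Of 7 matrix genes 1 passed, Zfp521, and 2 were higher adjusted over the list alone.

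**Figure D3:**
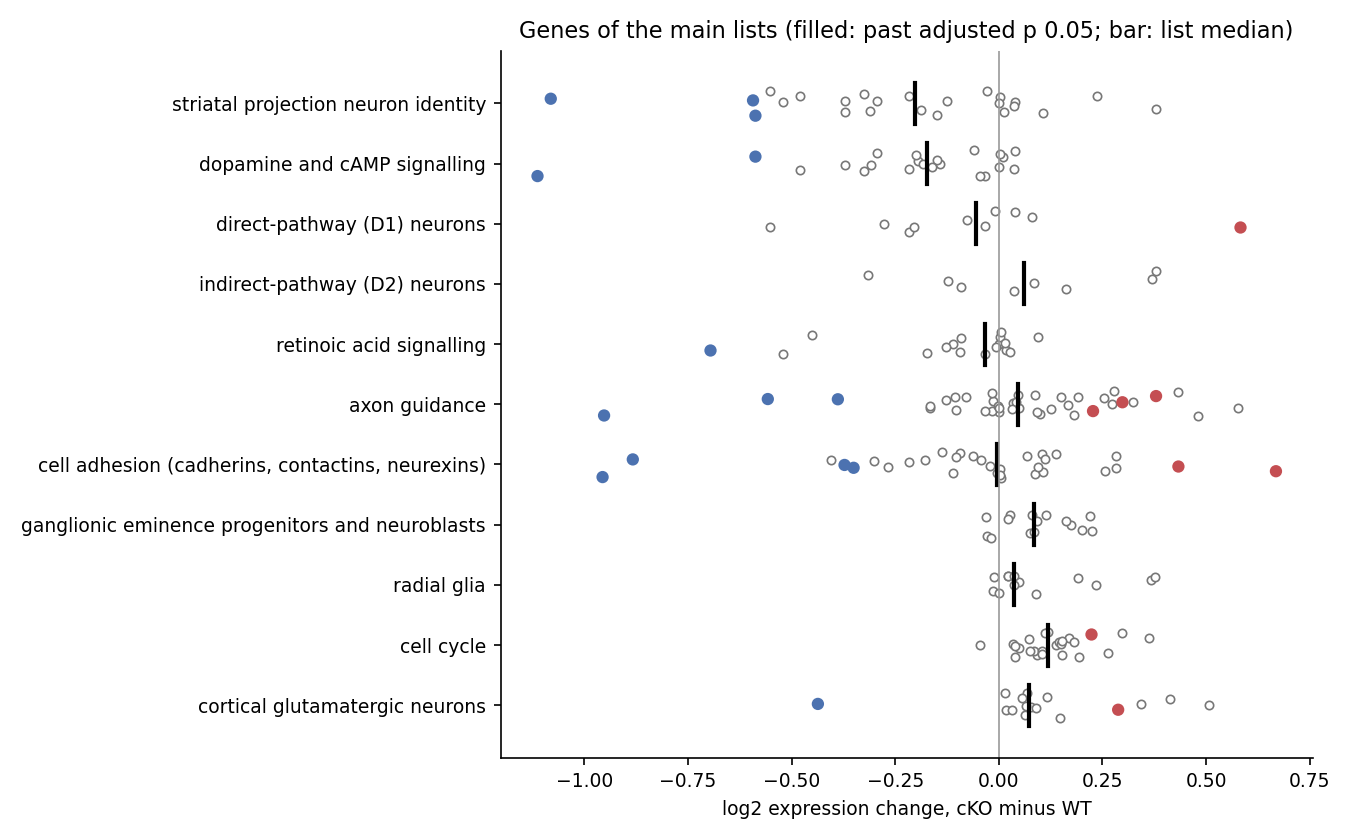
Log2 change, cKO minus WT, of each measured gene in 11 of the lists. Filled points passed an adjusted p of 0.05 over all genes (blue lower, red higher), open points did not, and the black bar is the list median. The projection neuron list has its median at -0.20 and the cell cycle list at 0.12.

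Genes of dividing and immature cells were higher as groups by camera with the preset correlation, mostly without single genes that passed. In the cell cycle list 24 of 25 measured genes had a positive change, and Aurkb, a mitotic kinase, rose by 0.22 ± 0.04, a call that held in 11 of 19 alternatives. In the test over the list alone, 3 were higher. The median was 0.12 and the adjusted p 3.34e-08 by camera, against an adjusted p of 0.347 with an estimated correlation. Its genes moved together from array to array, with an estimated correlation of 0.488. The list of ganglionic eminence progenitors and neuroblasts had a median of 0.085 (camera adjusted p = 0.000240, and adjusted p = 0.347 with an estimated correlation). Of its 15 measured genes 0 passed over all genes, 7 were higher at an unadjusted p under 0.05 in limma, and 6 were higher when adjusted over the list alone. Values were 0.08 ± 0.02 for Dcx, a microtubule protein of migrating neurons, and 0.22 ± 0.06 for the transcription factor gene Sox4. Without cKO replicate 6 Dcx passed (adjusted p = 0.0460). Radial glia genes had a median of 0.037 (adjusted p = 0.0129, and adjusted p = 0.497 with an estimated correlation), with values of 0.37 ± 0.09 for Sox2 and 0.23 ± 0.07 for Nes. Sox2 passed with dim probe sets left out (adjusted p = 0.0393) and with a trended, robust prior (adjusted p = 0.0454). Of 13 measured, 0 passed over all genes, 4 were higher at an unadjusted p under 0.05, and 2 when adjusted over the list alone. The list's adjusted p was 0.0746 without WT replicate 4, and 0.0546 and 0.0571 without cKO replicate 2 or 5. With the cortical covariate described below it was 0.195. Wnt genes had a median of 0.021 (adjusted p = 0.0172, and adjusted p = 0.347 with an estimated correlation). Of 24 measured, 0 passed over all genes in limma, 7 were higher and 1 lower at an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone. Values were 0.08 for the ligand gene Wnt5a and 0.06 for the receptor gene Fzd9, and Wnt5a passed without cKO replicate 3 (adjusted p = 0.0132). The list's adjusted p was 0.110 without WT replicate 4, 0.0603 without cKO replicate 5, and 0.412 when dim probe sets were left out. All 4 of these lists missed the threshold in the exact permutation test of list means, with an adjusted p of 0.160 for cell cycle, 0.110 for ganglionic eminence, 0.160 for radial glia and 0.160 for Wnt. By fry they missed it as well, with an adjusted p of 0.156, 0.0863, 0.258 and 0.144.

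Markers of cortical glutamatergic neurons, a neighbouring tissue, were higher in the list test (median 0.072, adjusted p = 0.0129, and adjusted p = 0.528 with an estimated correlation). Of 16 measured genes, Tle4, a transcriptional corepressor, rose by 0.29 ± 0.03 and Mef2c, a transcription factor, fell by 0.44 ± 0.08. In WT these 2 averaged 9.65 and 9.98, well above Neurod6, another gene of the list (5.97 to 6.95). Whether they report cortical cells in this tissue was not tested. Adjusted over the list alone, the counts were again 1 and 1, and Mef2c passed in 6 of 19 alternatives. Mean levels of the list were 6.75 ± 0.11 (SD, n = 6) in WT and 6.87 ± 0.17 (SD, n = 6) in cKO (exact permutation p = 0.177, adjusted p = 0.365), and the array means overlapped. By fry the adjusted p was 0.258. Neurod6, singled out after its values were seen, ran from 5.97 to 6.95 in WT and from 6.25 to 7.41 in cKO. The list's adjusted p was 0.0720 without WT replicate 3, 0.0538 and 0.0566 without cKO replicate 4 or 5, and 0.111 without WT replicates 3 and 6. With the level of 4 cortical genes as a covariate, added after the data were seen, the projection neuron median was -0.17 and the cortical median -0.013.

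Markers of other cell types gave no list call. Several of these lists lay near the median probe set of 5.71, where little change can be seen. Their WT means were 5.52 for erythroid cells, 5.62 for choroid plexus and ependyma, 5.87 for microglia and 5.90 for meninges. Among interneuron genes of the medial ganglionic eminence, Maf rose, and the chemokine receptor gene Cxcr4 fell by 0.42 ± 0.08, with a list median of 0.0012 (adjusted p = 0.489). Over the list alone, 2 were higher and 1 lower, and Cxcr4 passed in 10 of 19 alternatives. Medians were 0.016 for astrocytes (adjusted p = 0.656), 0.0022 for the oligodendrocyte lineage (adjusted p = 0.854), -0.015 for microglia (adjusted p = 0.678) and 0.043 for endothelial cells and pericytes (adjusted p = 0.305). They were 0.0024 for meninges (adjusted p = 0.788), -0.015 for erythroid cells (adjusted p = 0.394), -0.015 for choroid plexus and ependyma (adjusted p = 0.475) and -0.014 for pallidal, septal and diencephalic neighbours (adjusted p = 0.380). In limma 0 genes of these 8 lists passed over all genes. At an unadjusted p under 0.05 there were 2 higher and 1 lower among endothelial genes, 1 and 2 among microglial, 1 and 1 among meningeal, and 1 lower in each of the astrocyte, oligodendrocyte and neighbour lists, with 0 in the remaining lists. Adjusted over the list alone, 1 astrocyte gene was lower and 1 meningeal gene was higher and 1 lower. Values were -0.36 ± 0.10 for the astrocyte gene Sox9, which passed without WT replicate 1 (adjusted p = 0.0324), and 0.13 ± 0.05 for the pericyte gene Pdgfrb.

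**Figure D4:**
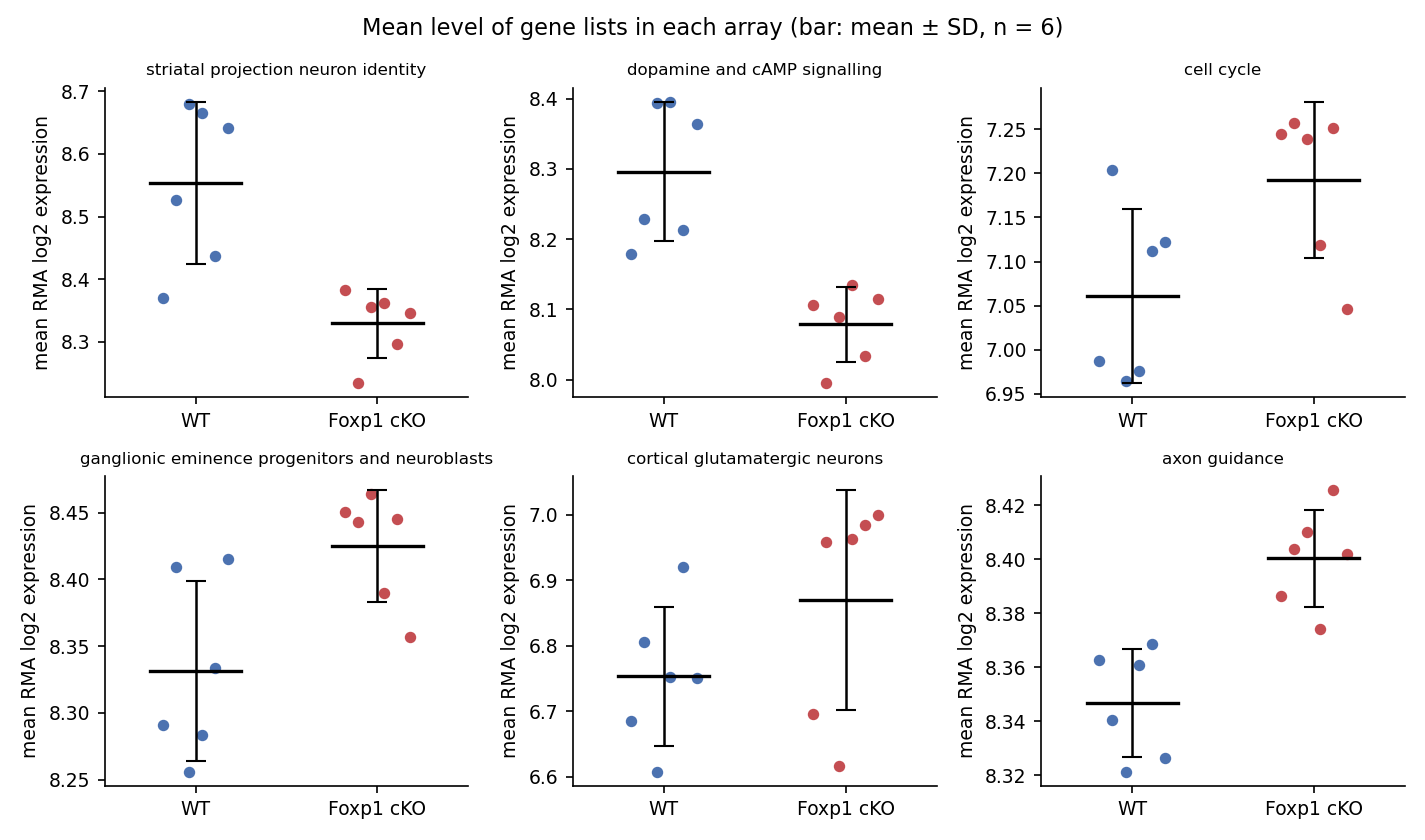
Mean log2 expression of 6 gene lists on each array (points), with the group mean and SD (bars, n = 6 per group); axes do not start at 0. The WT and cKO arrays were apart for dopamine and cAMP signalling and for axon guidance, and overlapped for the other 4 lists.

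Guidance and adhesion molecules changed in both directions. Of 39 axon guidance genes, 3 fell and 3 rose. The ephrin receptor genes Epha7 (-0.56 ± 0.04) and Ephb1 (-0.39 ± 0.06) fell with Plxnd1, and Dcc, a netrin receptor gene, rose by 0.38 ± 0.03. Slit3 (0.30) and Efnb2 (0.23), chosen after their values were seen, also rose. When adjusted over the list alone, 9 were higher and 3 lower. The list median was 0.046, with a camera adjusted p of 0.0211 and an adjusted p of 0.303 with an estimated correlation. That correlation was -0.0053, below the preset 0.01, and camera's unadjusted p with it was 0.00819. The list mean was 8.35 ± 0.02 (SD, n = 6) in WT and 8.40 ± 0.02 (SD, n = 6) in cKO (exact permutation adjusted p = 0.0320), with all 6 cKO arrays above every WT array. The call was lost by camera on ranks (adjusted p = 0.0810) and without WT replicates 3 and 6 (adjusted p = 0.0809). Of 33 cadherin, contactin and neurexin genes, 4 fell and 2 rose. Cdh8 and Cntn5 fell, Cdh4 rose by 0.43 ± 0.06 and Cntn3 rose. Cdh13 (-0.37) and Pcdh17 (-0.35), chosen after their values were seen, fell. The list median was -0.0034 (adjusted p = 0.192), and 9 were lower and 4 higher when adjusted over the list alone. It passed without WT replicate 6 (adjusted p = 0.0375) and without WT replicates 3 and 6 (adjusted p = 0.0447).

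Channel and receptor genes showed single changes without a list call. Among potassium channel genes Kcna4 fell by 0.29 ± 0.05 and Kcnab1 by 0.25 ± 0.05 (2 of 22 measured, list adjusted p = 0.477). Over that list alone, 2 were lower and 1 higher, and Kcnab1 passed in 8 of 19 alternatives. Both genes lay near the median probe set of 5.71, Kcna4 averaging 6.13 in WT and 5.84 in cKO and Kcnab1 6.08 and 5.83. Among sodium and calcium channel genes Cacna2d3 fell by 0.60 ± 0.09 and Cacna1h by 0.32 ± 0.05 (2 of 20, list adjusted p = 0.687), and 2 were lower when adjusted over the list alone. Without cKO replicate 2 Cacna1h had an adjusted p of 0.0544. Grik2, a kainate receptor gene, fell by 0.59 ± 0.04, 1 of 22 glutamate receptor and postsynaptic genes (list adjusted p = 0.249, with 2 lower and 1 higher when adjusted over the list alone). For GABA genes 0 of 15 passed over all genes in limma (list adjusted p = 0.475), with 4 higher and 3 lower at an unadjusted p under 0.05, and 3 higher and 2 lower when adjusted over the list alone. Values were -0.26 ± 0.06 for the GABA-A receptor gene Gabrb2 and 0.54 ± 0.14 for Gabra2. With dim probe sets left out both passed (adjusted p = 0.0261 and 0.0374). Gabrb2 also passed with a trended, robust prior (adjusted p = 0.0388), and Gabra2 without WT replicate 6 (adjusted p = 0.0171) and without WT replicates 3 and 6 (adjusted p = 0.0425). In the list of autism and speech-related genes, 2 of 19 fell, Mef2c and Reln (-0.45 ± 0.06), a secreted matrix protein (list adjusted p = 0.682). Over that list alone, 2 were lower and 1 higher.

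Genes near Foxp1 on chromosome 6 held 1 rise, Cntn3, and 1 fall, Eif4e3 (-0.23 ± 0.05), among 18 measured, with the same counts adjusted over the list alone. All 19 listed genes lie on that chromosome in the GRCm38.p6 assembly. The list median was 0.060 (camera adjusted p = 0.0437, and adjusted p = 0.347 with an estimated correlation), and the list passed in 7 of 23 alternatives. Without WT replicate 1, 3, 4, 5 or 6 its adjusted p was 0.0626, 0.0630, 0.0746, 0.0600 or 0.107, and without cKO replicate 2, 4, 5 or 6 it was 0.0546, 0.0618, 0.0575 or 0.0752. It was 0.136 without WT replicates 3 and 6, 0.107 by camera on ranks, 0.106 by fry and 0.280 with the cortical covariate. With array weights it was 0.0615 and with the Y-linked covariate 0.0523. Eif4e3 passed in 7 of 19 alternatives. Among immediate early genes 1 of 15 rose, Btg2 (0.15 ± 0.02), with a list adjusted p of 0.854, and 3 were higher and 1 lower when adjusted over the list alone. Without WT replicates 3 and 6 the adjusted p of Btg2 was 0.0637. Btg2 averaged 5.93 in WT and 6.08 in cKO, near the median probe set of 5.71.

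Genes of energy metabolism, stress and cell survival gave no call. In limma 0 of 37 respiratory chain genes passed over all genes (list median -0.0052, adjusted p = 0.475), 3 being lower at an unadjusted p under 0.05, with -0.14 ± 0.05 for Ndufs4, a complex I subunit. Values were likewise short of the threshold for mitochondrial biogenesis and mitophagy (adjusted p = 0.779), oxidative stress (adjusted p = 0.945), apoptosis (adjusted p = 0.171), Notch signalling (adjusted p = 0.779) and hypoxia and glycolysis (adjusted p = 0.899). At an unadjusted p under 0.05 in limma there were 2 higher and 2 lower among oxidative stress genes, 3 higher among apoptosis genes, 3 higher and 1 lower among Notch genes, 2 lower among hypoxia genes and 0 among mitochondrial biogenesis genes. Over each list alone, 1 Notch gene was higher and 0 genes of the other 5 lists passed. The list checking the Nestin-Cre transgene, with Gh at 5.50 in WT and 5.51 in cKO, had an adjusted p of 0.563. Gh lay below the median probe set of 5.71, too near the floor to report on the transgene. The titles name Nestin-Cre in the knockout group alone, so effects of Cre and of Foxp1 loss cannot be told apart. In limma 0 of 5 passed over all genes, 1 was higher at an unadjusted p under 0.05, and 1 member was higher when adjusted over the list alone.

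In all, 10 of the 37 lists passed camera with the preset correlation, 3 lower and 7 higher. With an estimated correlation 0 passed by camera (smallest adjusted p = 0.303), 4 having an unadjusted p under 0.05. The adjusted p of 0.347 is a value that the adjustment gave to several lists alike. Among the called lists that carry it, camera's unadjusted p ran from 0.0201 (dopamine and cAMP signalling) to 0.0896 (cell cycle). By fry, which asks whether the genes of a list move one way on balance, 2 passed, dopamine and cAMP signalling and axon guidance. Camera on ranks passed 7, without retinoic acid, axon guidance and the genes near Foxp1. The exact permutation test of list means passed 5, namely projection neuron identity, dopamine and cAMP signalling, retinoic acid, axon guidance and the genes near Foxp1. Median, mean and test differed in sign in 9 lists, 0 of them past the threshold.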

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

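The tests on the abundance of projection neuron genes and on choroid plexus genes were chosen after the results were seen, as were the cortical covariate and the removal of WT replicates 3 and 6 as settings. For the number of probe sets, a chance division of the arrays was unlikely. Of 100 of the 462 ways to divide the 12 arrays into 6 and 6, only 1, the real one, gave 185 probe sets or more, and the highest other gave 1. The other divisions mixed the genotypes, which can widen the spread within groups. A batch that follows genotype would pass the same test and was not tested. For gene lists chance could not be excluded: 9 of the 100 gave at least the 10 lists of the real division, and the highest other gave 13. Xist and Y-linked genes differed between arrays in both groups, and with the Y-linked level as a covariate 151 probe sets passed, 137 of them shared with the 185. Sex differences therefore do not account for the count as a whole, while a genotype effect that differs between sexes was not tested.

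The lower level of projection neuron genes was set against 3 explanations. A smaller share of these neurons would lower the abundant members alike only if other cells did not express them. Of the 14 members above a log2 level of 8, 5 had 95% intervals wholly above the list median (Foxp2, Drd2, Meis2, Penk and Zfp503). By chance 0.350 would be expected if genes were independent and shared 1 change, yet the list's estimated correlation was 0.364. Expression in other cells was not measured, so the values show unequal changes among members and cannot exclude a smaller share. With the cortical covariate the list median was -0.174 (camera adjusted p = 6.69e-05), and without WT replicates 3 and 6 it was -0.178 (camera adjusted p = 1.35e-05). The median thus stayed near its main value of -0.20, which argues against cortical tissue or those arrays as the whole cause. The limits are that both p values rest on the preset correlation, and that the cortical level itself was 0.353 higher in cKO. A smaller share of projection neurons, a loss of 1 class of them and altered expression within cells all stay open, and may act together. The genotype is the biological explanation the design gives, and the estimated-correlation adjusted p of 0.347 leaves the list's shift against other genes undecided.

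Ttr, the transthyretin gene of the choroid plexus, read 9.96 in cKO replicate 1 and between 5.39 and 5.57 on the other 11 arrays. Choroid plexus tissue in that sample could raise it. The other 10 choroid and ependymal genes lay above the other 5 cKO arrays by a median of only 0.0481 (upper limit 0.0730), and 4 of them were highest on that array, against 0.833 by chance. The bound set for excluding the explanation was met, but all 10 genes lie within 0.5 of the median probe set at 5.71, too near the floor to exclude anything, a limit that was added after the result was seen. Choroid tissue and a fault confined to Ttr cannot be told apart, and no biological explanation was tested.

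In 13 of 248 groups of 6 values 1 array lay far from the rest, against 12.4 expected by chance. Among genes in cKO, Cntn5 read 7.0107 in replicate 4 (nearest other 7.1777), Dcx 12.188 in replicate 6 (12.25), Ikzf1 6.276 in replicate 1 (6.1055) and Zfp521 9.4961 in replicate 2 (9.7871). Among genes in WT, Cxcr4 read 7.4814 in replicate 6 (7.1797), Npy1r 6.3984 in replicate 6 (6.7803), Islr 5.542 in replicate 3 (5.6533) and Sox4 11.188 in replicate 3 (11.475). Among list means in cKO, choroid plexus and ependyma stood at 6.0357 in replicate 1 (5.6101) and the Nestin-Cre checks at 5.7994 in replicate 6 (5.8547). In WT, the genes beside Foxp1 stood at 6.9563 in replicate 6 (7.0256), meninges at 5.939 in replicate 1 (5.8972) and oxidative stress at 7.6525 in replicate 3 (7.5553).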

How the results depend on the processing

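Cyclic loess, the removal of WT replicates 3 and 6, the cortical covariate and the exact permutation of list means were chosen after the data were seen. Foxp1 passed in all of its alternatives, with -0.96 to -0.86 when single arrays were left out. The 185 probe sets (76 higher, 109 lower) became 278 with 118 higher among probe sets above the median level, 30 (6 higher, 24 lower) with a 1.5-fold minimum, 61 (19 higher, 42 lower) at an adjusted p below 0.01, and 45 higher without WT replicates 3 and 6; fewer tested probe sets, a stricter limit or fewer arrays make part of these differences. Leaving out single arrays gave 106 to 227 in total, 39 to 93 higher, 66 to 134 lower and 6 to 11 lists. With the replicate number as a replicate block 64 passed (24 higher, 40 lower), 52 of them shared, and the D1 list passed (adjusted p = 0.0304). Same-numbered arrays correlated from -0.22 to 0.15 and 0 of 6 correlated best with their own number. The values thus gave no sign that the numbers pair the arrays, which does not exclude a shared litter or batch. With the block 25 calls of named genes were lost. Among them were the 3 called projection neuron genes, Foxo1 (limma adjusted p = 0.0900), Ikzf1 and Pde10a (each 0.0718). Most of the 12 largest named rises were lost as well. The 10 lists became 0 with an estimated correlation, 2 by fry, 7 by camera on ranks, 5 by exact permutation and 6 with the cortical covariate, which turned the cortical list to -0.013 because it holds 4 genes of that kind. Over 1658 comparisons of named genes 1511 kept their side of the threshold (1 of these had the other sign, never past it), 128 lost a call, 19 gained one and 0 reversed. For lists 779 of 847 kept their side, 38 of these with the other sign and never past the threshold. Of the rest, 57 were lost, 10 gained and 1 reversed. Both tallies include genes and lists without a main call, which had no call to lose. Among the 10 called lists, dopamine and cAMP signalling kept its call most often (22 of 23 alternatives). The genes near Foxp1 kept theirs least often (7 of 23). For other differences the cause was not tested. Quantile and median steps move almost nothing on columns that share a distribution, so they say nothing about stability and are left out of all such tallies. The trended, robust prior does not enter camera and is left out for lists alone. The mean of several probe sets per gene was not run, since each gene has 1. Signals near the median of 5.71 limit what can be seen of dim genes.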

Other observations

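The lists in the 2 closing paragraphs, their tests and every gene named here were chosen after the values were seen. Further genes outside the named set were lower in cKO. Tenm3, a teneurin, fell by 0.72 ± 0.08 (SE), Cntnap3, a contactin-associated protein gene, by 0.70 ± 0.12, and Lrrc4c, which encodes a netrin-G ligand, by 0.40 ± 0.04. Dlg2, a postsynaptic scaffold gene, fell by 0.30 ± 0.04, and Ppp3ca, a catalytic subunit of calcineurin, by 0.33 ± 0.04. Ntrk3, the neurotrophin-3 receptor gene, fell by 0.31 ± 0.04 and Gucy1a1, a subunit of the nitric oxide receptor, by 0.38 ± 0.06. Each had a limma adjusted p below the threshold of 0.05.

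Among the increased genes, Ntsr1, a neurotensin receptor gene, rose by 0.45 ± 0.07 and Acvr2a, an activin receptor gene, by 0.44 ± 0.08. Tshz1, a zinc finger gene, rose by 0.36 ± 0.05 and Wls, which carries Wnt ligands to the cell surface, by 0.37 ± 0.06. Dio3, which inactivates thyroid hormone, rose by 0.12 ± 0.02, while the thyroid hormone receptor gene Thrb fell by 0.18 ± 0.03; both lie near the floor of the arrays.

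Xist, which is active in female cells, read 11.5 to 11.6 in WT replicates 3 and 4 and cKO replicates 2, 3 and 5, and 5.47 to 5.69 on the other arrays, where the Y-linked genes were high. Between the genotypes, 0 of the 3 measured Y-linked genes passed in limma over all genes, over the list alone or at an unadjusted p under 0.05, and Xist had an adjusted p of 0.877. The removals that lowered the count most were those of cKO replicates 2, 5 and 3 (106, 109 and 117 probe sets).

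Gene families that appeared among the calls were tested as lists. They hold genes picked because they were called, so neither these tests nor counts over a list alone can decide whether the families moved. Of 27 measured imprinted genes 3 rose, Dlk1, Peg10 and Dio3, and 0 fell (camera adjusted p = 0.000931, and adjusted p = 0.228 with an estimated correlation). Adjusted over the list alone, 4 were higher, with Nnat (0.13), and 1 was lower, Igf2 (-0.19). Of 14 teneurins and partners 3 fell, Tenm2, Tenm3 and Lrrc4c, and 0 rose (camera adjusted p = 0.00120, and adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone, 6 were lower, with Flrt2 (-0.27), Tenm4 (-0.32) and Flrt3 (-0.41), and 1 was higher, the teneurin gene Tenm1 (0.18). That imprinted genes or teneurins may respond together to the genotype is a hypothesis these data leave open.

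Brain extracellular matrix genes went both ways, with 2 higher (Tnr and Spon1) and 3 lower (Gpc6, Reln and Vcan) of 19 measured, the same counts as over the list alone. Camera gave an adjusted p of 0.754, and 0.728 with an estimated correlation. By fry the adjusted p was 0.0330 for this list and for imprinted genes, 0.000614 for teneurins and 0.0657 for neurofilament and cytoskeleton genes. Fry cannot decide either, since these lists hold genes picked because they were called. Of 16 neurofilament and cytoskeleton genes 1 fell, Nefl (camera adjusted p = 0.0174, and adjusted p = 0.228 with an estimated correlation), and over the list alone Nefm (-0.25) was lower too, making 2. Ribosomal protein (adjusted p = 0.107), interferon (adjusted p = 0.875), cholesterol synthesis (adjusted p = 0.101) and heat shock lists (adjusted p = 0.962) gave no call, with 0 of their genes past the threshold over all genes or over the list alone in limma. At an unadjusted p under 0.05, 4 ribosomal, 1 cholesterol and 1 heat shock gene were lower, 0 were higher, and 0 interferon genes passed.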
